A study of Mus musculus with 24 samples.

How the data were processed

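Lungs of mice given an antibody against H-2Kb, a mouse MHC class I molecule, or an isotype-matched control antibody were profiled on 1-colour Agilent arrays. Per the labels, 200 µg of antibody per mouse was given into the airways of mice aged 8 weeks, and 24 arrays cover 2 antibodies, days 1, 2, 3 and 6, and 3 replicates in each of the 8 groups. The labels describe the times in different ways. The series design counts the days after antibody, whereas the treatment protocol gives antibody on these days with lungs taken 4 hours later, so a day here is the labelled day only. The labels number the replicates and do not say what else same-numbered samples share. Whether each replicate is a separate animal was not taken as given, so p-values measure the spread between these samples.

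The deposited intensity values are scanner output of the red (Cy5) channel, made per the file headers with Agilent Feature Extraction 11.5.1.1, whose processed signal has the background already subtracted. Each file held 44397 spots, of which 43020 were not controls and carried 39429 different probes. The authors' deposited series table holds intensity values that share 1 distribution in all 24 columns, with a median of 149.67 in each. Each of its 24 columns correlated best with its own array (lowest Spearman correlation 0.99992). The table is therefore on a linear scale and quantile normalised, and it was used as an alternative only.

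The 1377 control spots and 2821 spot values flagged as outliers were left out, and 0 spots were saturated. Log2 of the processed signal minus each array's 75th percentile over non-control probes was used, with spots of a probe averaged. The 75th percentile ran from 519 to 1565 over the arrays, and 45.1% to 59.8% of spots were well above background. The number of arrays limits the precision. Probes well above background on at least 3 of the 24 arrays were kept (23249 probes). For a gene with several kept probes (3720 genes), the probe with the highest mean was used, which left 18776 genes. Probes were named through RefSeq accessions of assembly GRCm38.p6 where these matched (28025 probes), otherwise by the file's symbol (3413), a synonym (295) or the file's own name (2036), and 5660 probes had no symbol. Coordinates are those of the file headers' annotation, build mm9, counted from 1.

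Comparisons were fitted with limma 3.58.1 in R 4.3.3, with lmFit on 8 group means over all 24 arrays, default eBayes and Benjamini-Hochberg adjustment at 0.05. The comparisons were anti-H-2Kb against isotype on each day and averaged over the 4 days, an F test for an antibody effect that differs between days, and an F test for change over days within isotype. Of 53 gene lists, 51 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. The list tests on the 4 days and their average were adjusted as 1 family. The arrays lie on 6 slides of 4, each scanned once, so slide and scan are the same batch. Slide was used as a fixed or random block, and differences within slides were computed wherever a slide held both antibodies of a day.

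The lists, comparisons, main settings, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, among genes past the threshold with groups that do not overlap (for the average, the same sign on all 4 days), the 10 highest and 10 lowest log2 fold changes with a true gene symbol. It adds up to 4 passing members of each list, or for a list past its own test with none, up to 2 members with the largest fold change, given as values. Where fewer than 10 genes pass on a day, it takes the 5 highest and 5 lowest values among genes at unadjusted p under 0.01 whose groups do not overlap, given as values that did not pass. It also takes the 10 symbols with the smallest p in each F test, and 19 genes whatever their result, of which 17 were measured. The text does not give values for all of these 17 genes. Il17a and Cxcl1 are only drawn, and Tnf, Cxcl9, Cxcl10, Scgb1a1, Sftpc, Col5a1, Tuba1a, Cd3e and Cd79a are left out. S100a8, Ccl2 and Foxj1 are given for single days only. None of the 17 passed on a single day in the main fit. A fold written as at least N-fold sets the brighter group's mean against the lowest signal among probes well above background, for a probe not well above background on any array of the dimmer group.

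The fit was tested on simulated data for the day 6 comparison with 18709 genes, 200 of them changed, in 20 draws. When whole arrays of real residuals were resampled, 92.3% of 4-fold, 41.6% of 2-fold and 5.37% of 1.5-fold changes were found. A mean of 19.7 unchanged genes was called along with them. Before any change was added, 1 of the 20 draws called genes (101 of them). The average over days was not simulated. In these draws camera at the preset correlation called a mean of 9.65 of the 51 lists where nothing had been changed, and at most 24. With an estimated correlation it called 0. Alternatives covered background correction, normalisation, the filter on dim probes, the probe rule, blocks, the groups in the fit, the eBayes settings, array weights, a fold threshold, other list tests and leaving out each array. Those chosen after seeing the data were the removal of the trend over probe GC content, covariates for negative control signal, the 75th percentile and the first principal component, eBayes with trend or robust alone, and leaving out 3 arrays.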

Results

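Gene expression was measured in whole lungs of mice after an antibody against H-2Kb (anti-H-2Kb), an MHC class I molecule present on nearly all cells, and after an isotype-matched control antibody. The design addresses which genes respond to the MHC class I antibody in a model of obliterative airway disease, the scarring of small airways seen after lung transplantation. There were 24 arrays in 8 groups of 3, with each antibody on days 1, 2, 3 and 6.

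H2-K1, the gene of the antibody's target, was measured well above background on all 24 arrays. The probe used lies on chromosome 17, 34133055 to 34133114 (mm9). The log2 fold change of H2-K1 in anti-H-2Kb against isotype was 0.04 on day 1, -0.11 on day 2, -0.12 on day 3 and -0.31 on day 6 (SE 0.165, n = 3 per group), and none passed the test (limma, smallest adjusted p = 0.2). With single arrays left out the day 6 value ran from -0.463 (without isotype day 6 replicate 1) to -0.17 (without isotype day 6 replicate 3), and it passed in 1 of 24 such fits. The 2 other probes of H2-K1 were also well above background on all 24 arrays and gave smaller day 6 values. On days 1, 2, 3 and 6 one gave -0.106, 0.165, 0.018 and -0.149, and the other 0.0447, -0.0168, -0.0552 and -0.165. B2m, the light chain of MHC class I, had a log2 fold change between -0.29 and 0.24 over the 4 days (SE 0.186) and did not pass either. Zbtb7a, a transcription factor, had log2 fold changes of 0.08, -0.21, -0.06 and 0.30 on days 1, 2, 3 and 6 (SE 0.265) by the probe at chromosome 10, 80614064 to 80614123. A dimmer probe of Zbtb7a at chromosome 10, 80607705 to 80607764, gave 0.52, 0.46, 0.81 and 1.18, so the 2 probes disagree. Both probes were well above background on all 24 arrays. The dimmer probe was not tested on its own, so a change of Zbtb7a stays open. The MHC class I antigen presentation list had median log2 fold changes between -0.04 and 0.06 and was not shifted by camera on any day. Ifng and Il6 were not measured above background: the Ifng probe was well above background on 0 arrays and the Il6 probe on 2.

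**Figure D1:**
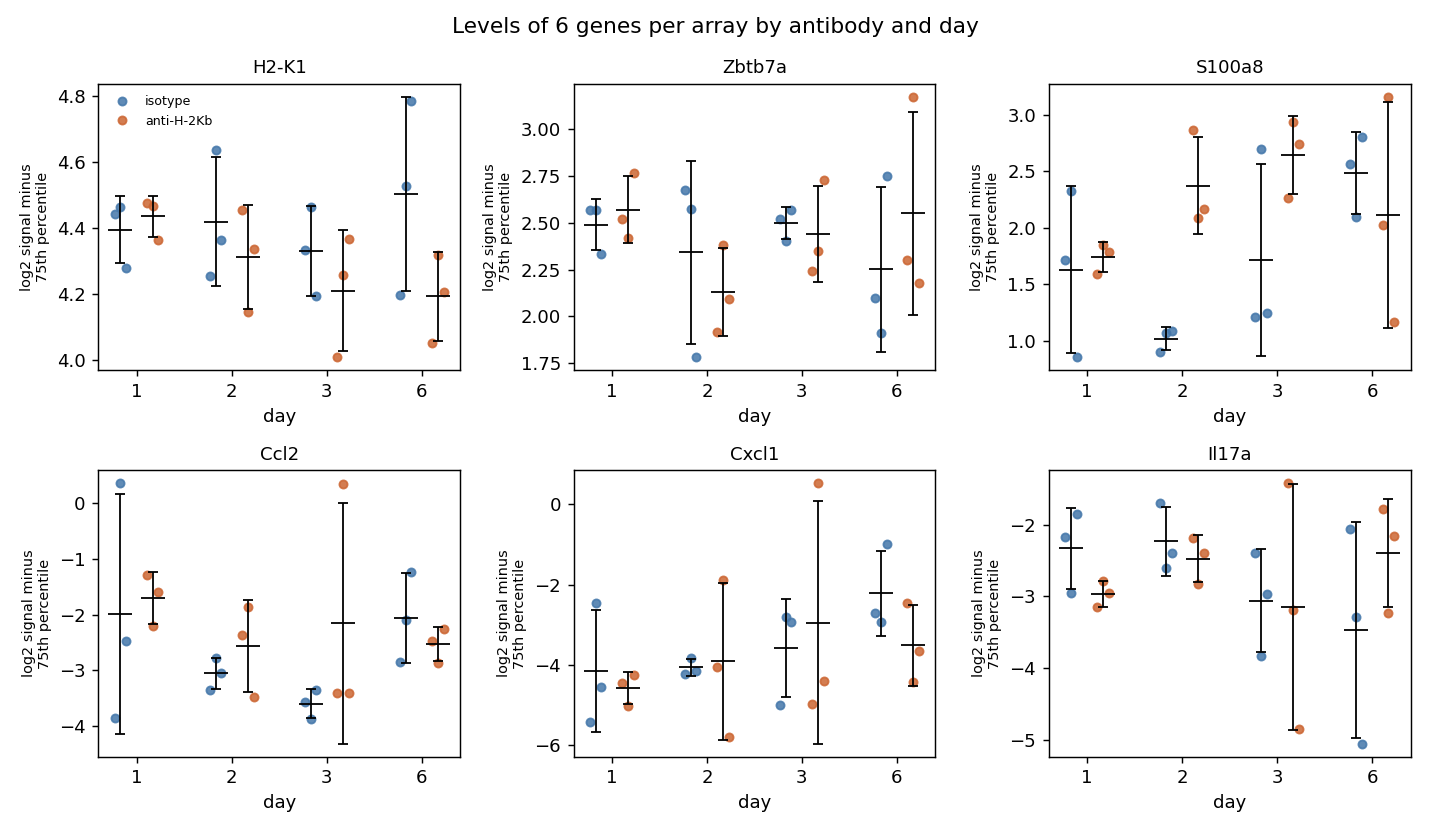
Log2 signal minus the array's 75th percentile (vertical axis) by day (horizontal axis) for H2-K1, Zbtb7a, S100a8, Ccl2, Cxcl1 and Il17a, with 1 point per array, a bar at the mean of 3 arrays and its SD. For Zbtb7a only the brighter probe is drawn, and a dimmer probe disagreed with it. S100a8 on day 2 had a mean of 2.37 in anti-H-2Kb and 1.02 in isotype, and Ccl2 on day 3 had an SD of 2.16 in anti-H-2Kb.

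On day 1, lungs given anti-H-2Kb had lower values of type I interferon stimulated genes than isotype lungs. Of 21 measured members 16 were lower, with a median log2 fold change of -0.26. Rsad2, an antiviral enzyme induced by interferon, had a log2 fold change of -1.18 ± 0.28 (SE, n = 3 per group) and Cmpk2 of -0.74 ± 0.25. Genes of the glucocorticoid response had a median of 0.26, with Sgk1 at 0.69 ± 0.221 and Errfi1 at 0.69 ± 0.329. Genes of alveolar type II cells, which make surfactant, had a median of 0.25, with Abca3, a surfactant lipid transporter, at 0.52 ± 0.165 and Cxcl15 at 0.39 ± 0.232.
By camera the interferon list was shifted lower (adjusted p = 0.00759) and the glucocorticoid (adjusted p = 0.0137) and alveolar type II (adjusted p = 0.022) lists higher. So were alveolar type I cells (median 0.17, adjusted p = 0.022, with Vegfa at 0.61 ± 0.192 and Timp3 at 0.50 ± 0.212) and the circadian clock (median 0.36, adjusted p = 0.0239, with Nfil3 at 0.73 ± 0.547 and Usp2 at 0.68 ± 0.243). Erythroid cells (median -0.49, adjusted p = 0.0301, with Hbb-b2 at -0.72 and Bpgm at -0.70) and thymus (median -0.42, adjusted p = 0.0301, with Cd8b1 at -0.77 and Arpp21 at least 1.16-fold lower) were shifted lower. Each of these 7 lists had adjusted p = 0.997 with an estimated correlation. No member passed over all genes tested; adjusted over the list alone, 2 members of the interferon list passed and 0 of the other 6.
Single arrays moved 4 of these medians by over 1.5 times: interferon to -0.162 (without anti-H-2Kb day 1 replicate 2), glucocorticoid to 0.163 and thymus to -0.255 (each without isotype day 1 replicate 3) and alveolar type I to 0.108 (without anti-H-2Kb day 1 replicate 1). So did the lowest values over single arrays left out for Nfil3 (0.229), Usp2 (0.434), Sgk1 (0.454), Timp3 (0.324), Cxcl15 (0.232) and Mfsd2a (0.811), and for Hbb-b2 the value nearest 0 (-0.424).
After normexp background correction none of the 7 lists passed (adjusted p from 0.0527 for erythroid cells to 0.649 for the glucocorticoid response). The medians were then -0.531 for erythroid cells and 0.413 for the clock, about as large as before. They were -0.134 for interferon, -0.0504 for thymus and 0.000617 for the glucocorticoid response, and had the other sign for alveolar type II (-0.0752) and type I cells (-0.101). With the first principal component as a covariate the glucocorticoid, clock, alveolar type I and II and thymus lists did not pass (adjusted p from 0.06 to 0.305). That component was taken from these same arrays, and its gene loadings correlated at 0.77 with the day 1 log2 fold changes. These losses therefore cannot tell the antibody from another source. With slide as a block the interferon list (median -0.30, adjusted p = 2.81e-05) and the erythroid list (median -0.35, adjusted p = 0.00267) passed, and the other 5 lists did not. The erythroid list did not pass with the replicate block (median -0.49, adjusted p = 0.0547). Slide 2 held both antibodies of day 1 (2 anti-H-2Kb arrays and 1 isotype array), and there the list means differed by -0.26 for interferon stimulated genes, -0.41 for erythroid cells, 0.02 for the glucocorticoid response, 0.14 for the circadian clock, 0.12 for alveolar type II cells, 0.20 for alveolar type I cells and -0.15 for thymus. The interferon means there were 0.189 and -0.294 in anti-H-2Kb and 0.203 in isotype. Isotype replicates 1 and 3 of day 1 lay on slide 3 and anti-H-2Kb replicate 3 on slide 4, so antibody and slide were largely confounded on day 1.
Across single genes limma called 0 of 18776 on day 1 (smallest adjusted p = 0.239). At an unadjusted p under 0.05 there were 1173 genes, array weights called 4486, and 15.2% of genes had groups that do not overlap, where chance gives 10%. Among values that did not pass, the amino acid transporter Slc38a4 was at least 1.77-fold higher in anti-H-2Kb, Gdap10 at least 1.09-fold, and Mfsd2a, Snhg11 and N6amt1 had log2 fold changes of 1.33, 1.18 and 1.04. Pdha2, Zdhhc22, Slc6a20a and Itpripl1 had log2 fold changes of -1.28, -1.23, -1.07 and -0.93, and Cbx2 was at least 1.09-fold lower.

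On day 2, lungs given anti-H-2Kb had higher values of T cell genes, with 19 of 20 members higher and a median log2 fold change of 0.24. Cd3d, a part of the T cell receptor complex, had 0.80 ± 0.313 (SE, n = 3 per group) and Cd8a 0.62 ± 0.241. Immediate early genes, which respond within minutes to stimulation, had a median of 0.33, with Atf3 at 1.17 ± 0.619 and Nr4a1 at 0.80 ± 0.403. S100a8, a neutrophil calcium-binding protein, had a log2 signal of 2.37 ± 0.428 (SD, n = 3) in anti-H-2Kb and 1.02 ± 0.103 in isotype, a difference that did not pass (limma, adjusted p = 0.604). Heart muscle genes were lower, with Actc1, a cardiac actin, at -0.82 ± 0.244 and Myh6, a cardiac myosin, at -0.61 ± 0.28.
By camera T cells (adjusted p = 0.00289), immediate early genes (adjusted p = 0.0224), erythroid cells (median 0.43, adjusted p = 0.0301, with Alas2 at 0.74 and Hbb-b2 at 0.74) and platelets (median 0.31, adjusted p = 0.0301, with Gp9 at 0.60 and Treml1 at 0.59) were shifted higher. Heart muscle (median -0.27, adjusted p = 0.00502) and adipose tissue (median -0.76, adjusted p = 0.00759, with Adipoq at -1.18 and Fabp4 at -1.08) were shifted lower. Each of these 6 lists had adjusted p = 0.997 with an estimated correlation. No member passed over all genes tested; adjusted over the list alone, 1 member of the heart muscle list passed and 0 of the other 5 lists. The adipose median was -0.38 without isotype day 2 replicate 2 (Adipoq -0.697, Fabp4 -0.613). The T cell median was 0.378 and the platelet median 0.471 without anti-H-2Kb day 2 replicate 2. The platelet median was 0.159 and Gp9 0.289 without anti-H-2Kb day 2 replicate 3, and without the same array Nr4a1 was 0.273 and Ppp6r3 -0.411. Cd3d was 0.467 and Cd8a 0.304 without anti-H-2Kb day 2 replicate 1, and Treml1 0.338 without isotype day 2 replicate 3. As deviations from the mean of all arrays, the T cell list means were 0.38, -0.101 and 0.0154 in anti-H-2Kb day 2. They were -0.16, -0.27 and -0.195 in isotype day 2, and in isotype this list was lower on day 2 than on day 1.
With negative control signal as a covariate immediate early genes, erythroid cells and platelets did not pass (adjusted p from 0.0901 to 0.0977), though their medians were about as large (0.325, 0.418 and 0.291). With the 75th percentile signal as a covariate immediate early genes (adjusted p = 0.0903), heart muscle and adipose tissue (each adjusted p = 0.0676) did not (medians 0.29, -0.227 and -0.592). Platelets did not pass after normexp (median 0.177, adjusted p = 0.0712) or with the GC trend removed (median 0.338, adjusted p = 0.128). Erythroid cells did not pass without the 3 arrays of highest adipose list (median 0.371, adjusted p = 0.0534) or with the replicate block (median 0.428, adjusted p = 0.0547). Heart muscle did not pass with no filter (median -0.253, adjusted p = 0.0551). All 6 lists passed with slide as a block, with medians of 0.27 for T cells, 0.49 for immediate early genes, 0.44 for erythroid cells, 0.57 for platelets, -0.34 for heart muscle and -1.12 for adipose tissue. Slide 6 held both antibodies of day 2, with 1 array of each. The list means differed there by 0.57 for T cells, 0.02 for immediate early genes, 0.33 for erythroid cells, 0.39 for platelets, -0.27 for heart muscle and -0.78 for adipose tissue. The other anti-H-2Kb arrays of day 2 lay on slides 3 and 5, and the other isotype arrays on slides 2 and 4. Antibody and slide were thus largely confounded on day 2 as well.
Across single genes limma called 0 of 18776 on day 2 (smallest adjusted p = 0.401), with 1482 at an unadjusted p under 0.05, and 0 with array weights. Groups did not overlap for 12.1% of genes, where chance gives 10%. Among values that did not pass, Rasal2 and Cntn6 had log2 fold changes of 1.35 and 1.48, Prl2a1 was at least 1.72-fold and Vmn1r80 at least 1.13-fold higher, and Cstdc5 was well above background on 1 of 3 anti-H-2Kb and 0 of 3 isotype arrays. Ppp6r3, Retreg3 and Armcx4 had -1.49, -1.43 and -1.20. Pln, a regulator of the cardiac calcium pump, was at least 1.82-fold lower and Erg, an endothelial transcription factor, at least 1.28-fold lower.

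On day 3, lungs given anti-H-2Kb had higher values of B cell and plasma cell genes, with 13 of 15 members higher and a median log2 fold change of 0.37. Jchain, the joining chain of secreted antibodies, had 1.25 ± 0.475 (SE, n = 3 per group) and Mzb1, a plasma cell chaperone, 0.57 ± 0.178. Genes of MHC class II antigen presentation had a median of 0.24, with H2-Oa at 0.58 ± 0.224 and H2-DMb2 at 0.55 ± 0.233. Genes of the extracellular matrix were lower, with Lox, a collagen crosslinking enzyme, at -0.99 ± 0.299 and Fbn1, fibrillin, at -0.75 ± 0.219. Adipose tissue genes were higher in 10 of 10 members, with Retn at 1.65 ± 0.652 and Car3 at 1.54 ± 0.626.
By camera B cells and plasma cells (adjusted p = 0.00517), MHC class II (adjusted p = 0.0301), mesothelium (median 0.41, adjusted p = 0.00195, with Lrrn4 at 0.81 and Krt19 at 0.60), adipose tissue (median 0.95, adjusted p = 0.000488) and CC and CXC chemokines (median 0.23, adjusted p = 0.0492) were shifted higher. Extracellular matrix (median -0.18, adjusted p = 0.00759), endothelial cells (median -0.21, adjusted p = 0.00303, with Lyve1 at -0.61 and Calcrl not well above background in either group) and the glucocorticoid response (median -0.15, adjusted p = 0.00759, with Fkbp5 at -0.98 and Tsc22d3 at -0.82) were shifted lower. With an estimated correlation none of the 8 held: B cells and plasma cells had adjusted p = 0.231 with an estimated correlation, mesothelium adjusted p = 0.604 with an estimated correlation, and the other 6 adjusted p = 0.997 with an estimated correlation. No member passed over all genes tested; adjusted over the list alone, 2 members of the extracellular matrix list, 2 of the glucocorticoid list and 1 of the mesothelium list passed, and 0 of the other 5.
The chemokine shift rested on 1 lung: without anti-H-2Kb day 3 replicate 2 the median was 0.002, and Ccl2 and Ccl7, which attract monocytes, were well above background on 1 of the 3 anti-H-2Kb arrays and 0 of the 3 isotype arrays. Single arrays also moved the adipose median to 0.48 (without anti-H-2Kb day 3 replicate 1), the matrix median to -0.07 (without the same array), the MHC class II median to 0.08 (without anti-H-2Kb day 3 replicate 3) the endothelial median to -0.141 (without anti-H-2Kb day 3 replicate 1) and the glucocorticoid median to 0.03 (without isotype day 3 replicate 3). Without anti-H-2Kb day 3 replicate 1, Jchain was 0.652, Retn 0.916 and Car3 0.732. In the other direction, single arrays left out moved the medians of MHC class II to 0.488, chemokines to 0.422, adipose tissue to 1.5, endothelial cells to -0.328, matrix to -0.272 and the glucocorticoid response to -0.302. Krt19 was 0.317 without anti-H-2Kb day 3 replicate 3, and Lrrn4 0.533 without isotype day 3 replicate 3.
Without the 3 arrays of highest adipose list, extracellular matrix (adjusted p = 0.297), endothelial cells (adjusted p = 0.159), the glucocorticoid response (adjusted p = 0.246) and adipose tissue (adjusted p = 0.0948) did not pass. Their medians were -0.072, -0.141, -0.043 and 0.476. Of the 3 arrays only anti-H-2Kb day 3 replicate 1 belongs to day 3, so these medians repeat the fit without that array. It was picked for its high adipose list, so a smaller adipose shift was fixed beforehand. MHC class II did not pass with quantile normalisation (median 0.07, adjusted p = 0.145), in the deposited series values (median 0.069, adjusted p = 0.342). Nor did it with the replicate block (median 0.238, adjusted p = 0.0547) or with negative control signal as a covariate (median 0.212, adjusted p = 0.0901). Chemokines did not pass after normexp (median 0.087, adjusted p = 0.219), with quantile normalisation (median 0.13, adjusted p = 0.0722), or in the series values (median 0.129, adjusted p = 0.0704). Nor did they with the replicate block (median 0.225, adjusted p = 0.0547), the negative control (median 0.223, adjusted p = 0.116) or 75th percentile covariate (median 0.202, adjusted p = 0.07). After normexp neither extracellular matrix (median -0.069, adjusted p = 0.0553) nor the glucocorticoid response (median -0.09, adjusted p = 0.0839) passed. With slide as a block 7 of the 8 lists passed, with medians of 0.33 for B cells and plasma cells, 0.32 for MHC class II, 0.46 for mesothelium, 0.90 for adipose tissue, 0.43 for chemokines, -0.17 for extracellular matrix and -0.20 for endothelial cells; the glucocorticoid list did not (median -0.02, adjusted p = 0.363). On slides 1 and 4, which held both antibodies of day 3, the list means differed by 0.34 and 0.26 for B cells and plasma cells, 0.38 and 0.36 for MHC class II, 0.43 and 0.44 for mesothelium, 0.67 and -0.09 for adipose tissue, 0.06 and 1.31 for chemokines, -0.21 and -0.07 for extracellular matrix, -0.21 and -0.03 for endothelial cells and -0.16 and 0.14 for the glucocorticoid response.
Across single genes limma called 0 of 18776 on day 3 (smallest adjusted p = 0.3), with 1234 at an unadjusted p under 0.05, and 493 with array weights. Groups did not overlap for 8.32% of genes, where chance gives 10%. Among values that did not pass, Ifi27l2a, an interferon-induced gene, had a log2 fold change of 1.31, Lgals7 1.32, Clec2d, a lectin-like receptor ligand, 1.22 and Pla2g2d 1.20, and Fcna was at least 1.69-fold higher. Myrip had -1.61, while Ampd3, Klhl24 and Rad54l2 were not well above background in anti-H-2Kb, with Ampd3 at least 1.65-fold and Klhl24 at least 1.48-fold lower. Dph2 was not well above background in either group.

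On day 6, lungs given anti-H-2Kb had lower values of the unfolded protein response, the response to misfolded protein in the endoplasmic reticulum, in 17 of 17 members. The median log2 fold change was -0.50, with Atf3 at -1.60 ± 0.619 (SE, n = 3 per group) and Dnajb9, a chaperone, at -0.79 ± 0.284. Clec2d had a log2 signal of 3.18 ± 0.273 (SD, n = 3) in anti-H-2Kb and 1.70 ± 0.554 in isotype, a log2 fold change of 1.48. Foxj1, the regulator of ciliated cells, had a log2 fold change of -0.66 ± 0.217, and the median of the ciliated cell list was 0.04. Neither gene passed (limma, adjusted p = 0.0507 for Clec2d and 0.0882 for Foxj1).
The unfolded protein response was shifted lower by camera (adjusted p = 0.00233; adjusted p = 0.997 with an estimated correlation), and was the 1 list called on day 6. No member passed over all genes tested, nor adjusted over the list alone (0 of 17). Both antibodies of day 6 lay on slides 1, 5 and 6, so the median with slide as a block was again -0.50, and the list means differed by -0.44, -0.73 and -0.36 on these slides. The median was -0.328 without isotype day 6 replicate 3. With the first principal component as a covariate the list no longer passed (median -0.187, adjusted p = 0.12). That component was taken from these same arrays, and its gene loadings correlated at -0.818 with the day 6 log2 fold changes. The loss of this list there therefore cannot tell the antibody from another source. In isotype this list was higher on day 6 than on day 1 in 17 of 17 members.
Across single genes limma called 0 of 18776 on day 6 (smallest adjusted p = 0.0507), although 5631 genes (30.0%) had an unadjusted p under 0.05, where 939 would by chance. The real split gave the most of the 10 splits of these 6 arrays, with 5536 the highest and 398 the median of the others. Groups did not overlap for 26.7% of genes, where chance gives 10%. The median of all genes was 0.14 at this scaling. Fits with the mean of all probes of a gene (230 genes), slide as a random block (1850), the replicate block (2131), negative control signal as a covariate (1474) and array weights (10242) called genes, and slide as a fixed block called 0. Without isotype day 6 replicate 1 there were 5396. Among values that did not pass, Prr30, Cdh15, Adamtsl5 and Tmprss9 had log2 fold changes of 1.38, 1.29, 1.24 and 1.23 (Cdh15 0.812 and Adamtsl5 0.763 without isotype day 6 replicate 2). Retreg3 and Afap1l2 had -1.90 and -1.66, while Ptpn21, a phosphatase, was at least 1.43-fold and Yes1, a Src family kinase, at least 1.21-fold lower in anti-H-2Kb.

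Averaged over the 4 days, 226 genes changed in lungs given anti-H-2Kb against isotype (limma, adjusted p under 0.05), of which 43 rose and 183 fell. Among those that rose on average, with a positive log2 fold change on each of the 4 days, were Rexo1 (log2 fold change 0.55 ± 0.0782 SE, 12 arrays per antibody, adjusted p = 0.0111), Laptm5, a lysosomal protein of blood cells (0.60 ± 0.0977, adjusted p = 0.0151), and Tgfb2, a growth factor of the TGF-beta family (0.55 ± 0.128, adjusted p = 0.0463). Among those that fell on average, with a negative log2 fold change on each day, were Cbx2, a Polycomb protein (-1.09 ± 0.192, adjusted p = 0.0224), Armcx1 (-0.89 ± 0.146, adjusted p = 0.0151) and Calcrl, the receptor of adrenomedullin and CGRP (-0.95 ± 0.233, adjusted p = 0.0494). The changes were small: 5 genes rose and 64 fell by at least 1.5-fold.
No gene passed on a single day. Others that rose on average, with a positive value on each day, were Acoxl (0.62), Gng8 (0.59), Rbpjl (0.57), Bmp1, a procollagen protease (0.55), Wfikkn1 (0.53), Smim41 (0.50) and Tmem88 (0.50). Others that fell on average, with a negative value on each day, were Nxpe3 (-1.06), Igip (-0.998), Armcx4 (-0.90), Lratd2 (-0.82), Pgm2l1 (-0.79), Runx1t1 (-0.78) and Usp40 (-0.78). On day 1 the value of Igip was -0.00188. These genes that fell were not well above background on all arrays, so their log2 fold changes rest partly on signals not well above background: of 12 anti-H-2Kb and 12 isotype arrays, Calcrl, Armcx4 and Lratd2 were well above background on 1 and 5, Armcx1 on 1 and 6, Usp40 on 1 and 9, Nxpe3 on 2 and 5, Cbx2 on 2 and 8, Runx1t1 on 3 and 8, Igip on 4 and 10 and Pgm2l1 on 6 and 11. Wfikkn1, which rose, was on 10 and 5.
From the fixed lists, Tgfb2 of the growth factors of airway obliteration, Zbtb20 (-0.50, adjusted p = 0.0457), the glucocorticoid-induced Tsc22d3 (-0.43, adjusted p = 0.0451), Clock of the circadian clock (-0.72, adjusted p = 0.0298, well above background on 4 and 8 of 12 arrays), the mast cell receptor Kit (-0.57, adjusted p = 0.0451) and Calcrl of endothelial cells passed over all genes tested. Endothelial cells were shifted lower by camera (median -0.12, 15 of 22 members lower, adjusted p = 0.0107; adjusted p = 0.997 with an estimated correlation), with 5 members passing adjusted over the list alone, and with slide as a block (median -0.12, adjusted p = 0.00442). They did not pass without the 3 arrays of highest adipose list (median -0.083, adjusted p = 0.118) or with the first principal component as a covariate (median -0.088, adjusted p = 0.124). The gene loadings of that component, taken from these same arrays, correlated at -0.586 with the average log2 fold changes. The loss with this covariate therefore cannot tell the antibody from another source. Within slides the endothelial list means differed by -0.09 on day 1 (slide 2), -0.22 on day 2 (slide 6), -0.21 and -0.03 on day 3 (slides 1 and 4) and -0.24, -0.23 and -0.06 on day 6 (slides 1, 5 and 6). The other 50 lists were not called, among them neutrophils (median 0.13, adjusted p = 0.435), the IL-17 list (median 0.04, adjusted p = 0.745) and extracellular matrix (median -0.02, adjusted p = 0.146).
With slide as a block 377 genes were called, 215 of them shared with the 226 and in the same direction. The count was 0 after normexp background correction and 8 without isotype day 2 replicate 2, and it reached 906 without anti-H-2Kb day 2 replicate 3.

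By the F test limma called 0 of 18776 genes as differing between days in the antibody effect (smallest adjusted p = 0.276), with 2525 genes at an unadjusted p under 0.05. The 10 symbols with the smallest p were Slc38a4, Fbxo28, Zdhhc20, Cacna1c, Ptpn21, Clec2d, Pln, Bdh1, Cyyr1 and Cbfa2t2. Slc38a4 was at least 1.77-fold higher in anti-H-2Kb on day 1 and at least 1.52-fold lower on day 6, with log2 fold changes of -0.30 and -0.85 on days 2 and 3 (SE 0.301). Clec2d had -0.79, 0.64, 1.22 and 1.48 on days 1, 2, 3 and 6 (SE 0.297). On the same days Cacna1c, a cardiac calcium channel, had 0.48, -0.63, -0.99 and -1.19 (SE 0.212). With slide as a block 1 gene was called, and with array weights 11396.

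Within isotype, camera called 21 list and day pairs against day 1, and 0 with an estimated correlation. The isotype arrays of day 1 lay on slides 2 and 3. Those of day 2 lay on slides 2, 4 and 6, those of day 3 on slides 1, 4 and 5, and those of day 6 on slides 1, 5 and 6. Day and slide were therefore largely confounded in these comparisons with day 1. Interferon stimulated genes were lower on day 2 (median log2 fold change -0.31) and day 3 (median -0.35) than on day 1, and the unfolded protein response was higher on day 6 (median 0.54). T cell genes were lower on day 2 (median -0.38, 19 of 20 members) and genes of surfactant lipid and cholesterol synthesis were higher on day 6 (median 0.46, 15 of 17 members). Esm1, an endothelial proteoglycan, had log2 fold changes against day 1 of 0.85, 1.36 and 1.21 on days 2, 3 and 6 (SE 0.217), and Rsad2 had -1.45, -1.44 and -0.52 (SE 0.28).
By the F test limma called 0 of 18776 genes over days (smallest adjusted p = 0.0706; 2258 at an unadjusted p under 0.05; 29 with slide as a block, 8119 with array weights). Against day 1 alone, limma called 0 genes on day 2, 6 on day 3 (all higher) and 22 on day 6 (13 higher, 9 lower), among them Esm1 on day 3 (adjusted p = 0.0259) and day 6 (adjusted p = 0.0291). The other symbols with the smallest p in the F test were Ly6a2, Tmtc2, Ift80, Asns, Cbfa2t2, Ifitm6, Rbpms2 and Csgalnact1. Camera called 8 lists on day 2, 9 on day 3 and 4 on day 6 against day 1, and 7, 4 and 3 of these also passed in the same direction with slide as a block. The interferon list had adjusted p = 0.955 with an estimated correlation on day 2 and adjusted p = 0.814 with an estimated correlation on day 3. The unfolded protein response and surfactant lipid lists on day 6, and T cells on day 2, each had adjusted p = 0.814 with an estimated correlation.

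**Figure D2:**
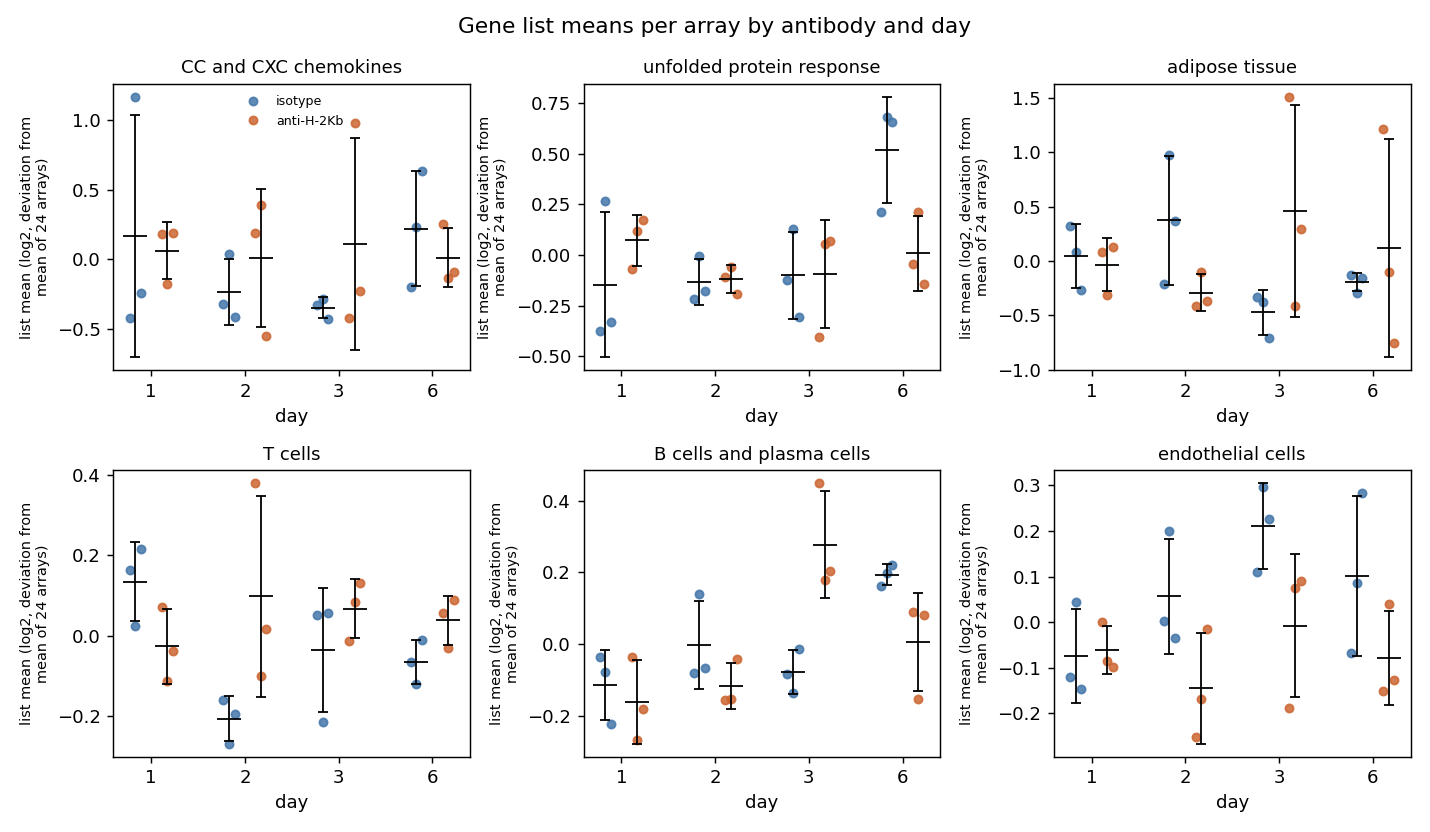
Mean over a list's members of the log2 deviation from the mean of 24 arrays (vertical axis) by day (horizontal axis) for 6 gene lists, with 1 point per array, a bar at the mean of 3 arrays and its SD. The chemokine list reached 1.17 in isotype day 1 replicate 2 and 0.98 in anti-H-2Kb day 3 replicate 2, and the adipose list 1.51 in anti-H-2Kb day 3 replicate 1.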

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

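The tests of array background, probe GC content, signal strength, fat tissue in 1 lung and splits matched to slides were chosen only after the patterns were seen in the data. Antibody shifts of 8 list and day pairs differed from that of day 1 by a test of the difference (camera, preset correlation). T cells (0.451) and erythroid cells (0.85) had a higher median shift on day 2 than on day 1, and alveolar type II cells a lower one (-0.428). On day 3 against day 1, interferon stimulated genes (0.393) and adipose tissue (0.94) were higher, and extracellular matrix (-0.426) and the glucocorticoid response (-0.57) lower. The unfolded protein response was lower on day 6 than on day 1 (-0.768). Each had adjusted p = 0.952 by camera with an estimated correlation. Of 100 splits of the arrays within days, 97 gave at least 8 such pairs, so chance cannot be excluded. The median of the other splits was 29 pairs and the highest 58. All 8 share the day 1 arrays. Alveolar type II cells, the glucocorticoid response and adipose tissue did not pass with slide as a block.

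Unadjusted day 6 differences were many (5631 genes), though none passed in limma. For an array background level, 2 settings went opposite ways: with negative control signal as a covariate 6769 genes had an unadjusted p under 0.05, and after normexp background correction 2282, so it stays open. Removal of the trend over probe GC content left 3439, between the bounds set for this test, so GC content stays open for part of the pattern. The difference on slide 6, whose pair had nearly equal signal, correlated across genes at 0.241 with that on slides 1 and 5, also between the bounds. Slides 1 and 5, whose anti-H-2Kb arrays were dimmer, correlated at 0.815 with each other and at 0.283 and 0.183 with slide 6, and with the 75th percentile signal as a covariate 3065 genes were left, so signal strength stays open. The day 6 count was the highest of the 10 splits of these 6 arrays, which are too few for a share under 0.05; the highest other was 5536 and the median of the others 398. An effect of the antibody on day 6 stays open as well.

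For the 226 genes changed on average, 2 of 100 splits within days gave as many, the real one included, a share under 1 in 20. That share was not adjusted for the other counts tested with splits. The other split gave 1942 genes, which points to a structure of the samples beyond antibody (its labels accounted for 0.22 of the largest axis of variation, the real ones for 0.061). It left 2 slides with arrays of 1 label only, against 0 in the real split. Few such splits reached the real count, but chance cannot be excluded. Among splits that keep the number of arrays of each antibody on every slide, 2 of 100 gave at least 226 (highest other 744), and with slide as a fixed block 4 of 100 gave at least the real 377 (highest other 3749). No splits were matched on replicate number. For the background level, all 226 passed with negative control signal as a covariate, but 0 after normexp background correction. Their median log2 change in the original direction went there from 0.502 (median SE 0.113) to 0.25 (median SE 0.138). That correction adds an offset of 50, which by itself shrinks log2 changes of dim probes whatever their cause. The smaller change there therefore cannot decide, and the background level stays open. After removal of the GC trend 31 of them passed, with a median of 0.4 (median SE 0.0993), and GC content stays open for part of these genes. With the 75th percentile signal as a covariate 129 passed, but the median was 0.489 (median SE 0.109), 0 of the 226 fell below 50% of their change and their highest unadjusted p was 0.000951 (0.000601 in the main fit). The calls lost there therefore do not support signal strength, though too few passed for the bound set to exclude it. An effect of the antibody stays open as well.

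The adipose list on day 3 (median 0.949) was at 0.476 without anti-H-2Kb day 3 replicate 1. That is close to the bound for fat tissue in 1 lung, but this bound was written only after the result. Fat tissue in 1 lung stays open. Leaving out the array picked for its highest list mean lowers this difference whatever the cause, so the fall by itself decides nothing. The levels of that list were also high in isotype day 2 replicate 2 (0.972) and anti-H-2Kb day 6 replicate 1 (1.21). No other technical explanation was tested for it.

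Within each day the 6 arrays make 10 splits, too few for a share under 0.05. For single genes the real count was 0 on each day; all 10 splits gave at least as many, and the highest other was 0 on days 1, 3 and 6 and 1 on day 2. For lists, the real 7 on day 1 stood beside a highest other of 19 (9 splits as large), 6 on day 2 beside 10 (6 splits), 8 on day 3 beside 14 (7 splits) and 1 on day 6 beside 14 (10 splits). The median of the other splits was 11, 6, 9 and 7 lists on days 1, 2, 3 and 6. The real list count was thus not above that median on any day. For the average over days 99 of 100 splits gave at least 1 list, with 20 the highest other and 8 the median. For the antibody effect between days all 100 splits gave at least the real 0 genes (highest other 3). Within isotype, 100 of 100 splits gave at least 0 genes (highest other 2858, which points to a structure of the samples that was not traced). Of these 100 splits, 69 gave at least the real 21 list and day pairs (highest other 51, median 28). Chance cannot be excluded for the list counts on single days, averaged over days or within isotype.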

How the results depend on the processing

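The alternatives chosen only after seeing the data were the removal of the GC trend, the covariates for negative control signal, the 75th percentile and the first principal component, eBayes with trend or robust alone, and leaving out the 3 arrays of highest adipose list. The cause of each difference was not tested. Genes called per day stayed at 0 under background correction, normalisation and filter alternatives. On day 6 limma called 230 genes with the mean of all probes, 1850 with slide as a random block (consensus correlation 0.219), 2131 with the replicate block, 1474 with negative control signal as a covariate and 10242 with array weights. Array weights also called 4486 on day 1 and 493 on day 3, 2741 on average, 11396 between days and 8119 over isotype days; its weights ran from 0.198 to 4.36 and were estimated gene by gene, since the default method stopped without converging. Negative control signal as a covariate called 2 on day 2.
For the average (226 genes), normexp called 0, quantile normalisation 48, median centring 38, the deposited series values 45, no filter 24, the stricter filter 140, slide as a fixed block 377, slide as a random block 887, the replicate block 698, eBayes with trend and robust 126, trend alone 131 and robust alone 175, a 1.5-fold threshold 69, the GC trend removed 32 (13 higher, 19 lower, against 43 and 183), negative control signal 1100, the 75th percentile signal 138, the first principal component 481 (202 higher, 279 lower) and leaving out the 3 adipose-high arrays 3. Slide as a fixed block called 1 gene between days. Over isotype days, quantile normalisation called 2, the deposited series values 2, the stricter filter 1, slide as a fixed block 29, slide as a random block 5, the replicate block 71, eBayes with trend and robust 1, trend alone 1, the first principal component 4 and negative control signal 5.
The labels do not say what a replicate number shares. Not every pair of the same number passed 0.1: 6 of 12 pairs between the antibodies of a day correlated over it, from -0.468 to 0.433, and 49 of 84 pairs over all groups. As a hint from the data, 15 of 24 arrays correlated best with their own number. Replicate number also accounted for 0.333 of the largest axis of variation (R2, permutation test, adjusted p = 0.0417). Arrays of number 2 lay on slides 1, 2, 4 and 5 and none on slides 3 and 6. Slide accounted for 0.555 of that axis, so these values cannot tell replicate number from slide. Shared work among arrays of 1 number stays open. The replicate block moved the counts as given and no list count by over 1.5 times. It did lose 4 list calls by camera, each at adjusted p = 0.0547 with a median about as large. These were erythroid cells on days 1 and 2, and chemokines and MHC class II on day 3.
For lists, camera with an estimated correlation and fry called 0 in all 7 list results (main 7, 6, 8 and 1 on days 1, 2, 3 and 6, 1 on average, 8 between days, 21 within isotype). Normexp called 2 on day 1, 6 on day 6, 6 on average and 2 between days. Quantile normalisation called 5 on day 6, 2 on average and 23 between days, and the deposited series values 5, 2 and 18. No filter called 11 on day 6, 4 on average, 18 between days and 32 within isotype. Slide as a fixed block called 14, 14, 13 and 3 on the 4 days, 2 on average, 33 between days and 32 within isotype. The GC trend removed called 3 on day 6, 2 on average and 13 between days, negative control signal 2 on average, and the 75th percentile signal 2 on day 6. The first principal component as a covariate called 11 on day 2, 15 on day 3, 2 on day 6, 7 on average and 30 between days. Leaving out the 3 arrays called 3 on average. Directions turned too. On day 1 normexp called 0 higher and 2 lower, the first principal component 0 higher and 6 lower and slide as a fixed block 1 higher and 13 lower (main 4 and 3). On day 6 (main 1 lower) the first principal component called 2 higher, and on average (main 1 lower) it called 7 higher and leaving out the 3 arrays 3 higher; the main call was lost in each. Leaving out the 3 arrays called 12 higher and 0 lower on day 3, normexp 10 and 1 and quantile normalisation 3 and 4 (main 5 and 3). On day 2 (main 4 higher, 2 lower) negative control signal called 1 higher and 3 lower and the 75th percentile signal 4 higher and 0 lower.
After normexp the medians of alveolar type II (-0.0752) and type I cells (-0.101) on day 1 turned negative. Without isotype day 3 replicate 3 the glucocorticoid median on day 3 was 0.0268, the highest over single arrays left out (lowest -0.302).
With single arrays left out, genes called ranged from 0 to 1 on day 1, 0 to 10 on day 2, 0 to 2 on day 3, 0 to 5396 on day 6, 8 to 906 on average, 0 to 1 between days and 0 to 24 over isotype days. Lists ranged from 5 to 11 on day 1, 3 to 10 on day 2, 5 to 18 on day 3, 1 to 4 on day 6, 1 to 3 on average, 4 to 18 between days and 15 to 31 within isotype.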

Other observations

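Chemokine genes were far apart between lungs of a single group, under either antibody. The mean of the CC and CXC chemokine list was 1.17 in isotype day 1 replicate 2 against -0.42 and -0.24 in the other 2 arrays of its group. It was 0.98 in anti-H-2Kb day 3 replicate 2 against -0.42 and -0.23, and 0.63 in isotype day 6 replicate 3 against -0.20 and 0.23. Interferon gamma response genes were likewise at 0.99 in isotype day 1 replicate 2 and 0.60 in isotype day 6 replicate 3. Heart muscle genes were at -0.30, -0.45 and -0.33 in the 3 anti-H-2Kb day 2 arrays. No test was run on these values, and the arrays were singled out after their values were seen.

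The largest axis of variation over the 24 arrays held 40% of the variance. Slide accounted for 0.555 of it (R2, permutation p = 0.0086, adjusted 0.0401), replicate number for 0.333 (permutation p = 0.0149, adjusted 0.0417) and antibody for 0.061 (permutation p = 0.243, adjusted 0.34). Slide and replicate number overlap, since slides 3 and 6 held no array of number 2. The scores of this largest axis went with negative control signal (Pearson r = 0.535, permutation p = 0.00716, adjusted 0.0401, and Spearman rho = 0.559, permutation p = 0.00506, adjusted 0.0401). Without the 2 arrays farthest from the median, r was 0.56. Within slides, with both values centred on the slide mean and permuted within slides, r was 0.095 (permutation p = 0.659, adjusted 0.71), a test chosen after the other values were seen. The adjustment covers 14 tests of the first 2 axes. Across genes, which are not independent replicates, its loadings correlated at -0.818 with the day 6 log2 fold changes, at 0.77 with those of day 1 and at -0.586 with the average. The next axis held 14.4% of the variance, and antibody accounted for 0.174 of it (R2, permutation p = 0.0421, adjusted 0.0854). Its scores went with negative control signal (Pearson r = 0.499, permutation p = 0.0126, adjusted 0.0417), though Spearman rho was 0.357 (permutation p = 0.0872, adjusted 0.153). Its loadings correlated at 0.608 with the average log2 fold changes and at 0.573 (Spearman) with probe GC content.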
